A study of Mus musculus with 6 samples.

How the data were processed

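Per the labels' protocols, RNA of sorted prostate basal cells was purified with a micro-scale column kit, and sequencing libraries were made with a low-input RNA kit (Ovation Solo). Per the submitters' processing notes, reads were checked with FastQC, trimmed with Trimmomatic, aligned to the mouse genome (GRCm38) with STAR 2.7.5a, checked with Picard and assigned to genes with HTSeq 0.11.1. The strand setting of the assignment is not stated.

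The deposited values are treated as a score, because they are neither whole reads nor a stated unit. The values themselves show what the labels do not state: in each library they sit on regular steps, between 1.0941 and 1.4534 units wide, and every library sums to between 20012882 and 20015378. Reads divided by the library's number of assigned reads, multiplied by a common total just under these sums and rounded up gave the listed values for at least 99.92% of genes in every library. The reads recovered in this way numbered between 13761287 and 18279236. The file held 49671 gene identifiers, and 99.31% of them were in the GENCODE M21 annotation, which supplied positions and biotypes. Of those found, 95.63% had the same symbol, and 101 symbols belonged to more than 1 identifier. Every column of values was matched to a sample.

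The design written before the data were examined assumed whole counts and a count-based test. Since the values are scaled and rounded, limma was used in its place. Values were taken as log2(value + 1), without further scaling. Genes were tested where at least 2 libraries had 20 units or more, which is 1 CPM on this scale, and 17598 genes met this. One linear model with a mean per group was fitted to the 6 libraries, which leaves 3 residual degrees of freedom, and the variance was moderated along an intensity trend with robust empirical Bayes (median prior degrees of freedom 6.48). The p-values were adjusted by Benjamini and Hochberg's method within each of the 3 comparisons, with a threshold of 0.05. The tests are two-sided.

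Gene lists were fixed before the data were examined: 37 lists of mouse genes for cell identity, inflammation, metabolism, growth, signalling and markers of other cell types. Lists with at least 5 tested genes, 34 in all, were tested against the other genes with limma's camera, at its preset correlation between genes of 0.01. The p-values were adjusted over the 34 lists of a comparison. Camera was repeated with the correlation estimated for each list, and no list passed in that form in any comparison. In each, 2 lists had an unadjusted p under 0.05, and the lowest adjusted p was 0.492, 0.476 and 0.354 in the order of the report. That form takes its p from a t distribution with the 3 residual degrees of freedom, whereas the preset form does not. Over 34 lists a pass was therefore hard to reach whatever the size of the change, and not passing says little. Counts adjusted over the list alone apply the Benjamini and Hochberg method within a single list.

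The genes named in the text were set by a rule. For each comparison these are the 8 genes with the highest and the 8 with the lowest log2 fold change among those past the threshold, with a mean of at least 5 CPM, no overlap between the libraries of both groups and no clone-type symbol. To them come up to 4 called members of each list that passed or held at least 3 called genes, by size of change, shortened to 2 where over 30 genes would be named, and 9 fixed genes. After the values were seen the text was shortened further, so that most lists that did not pass appear as counts. Genes named because they moved against their list, genes that moved the same way in both comparisons, genes given for contrast though they did not pass, and Gt(ROSA)26Sor were chosen after their values were seen, and for those outside the rule the calls were not recomputed with libraries left out.

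Means and SDs are over the 2 libraries of a group in the deposited unit, and log2 fold changes carry the moderated model's SE. The overlap of comparisons that share libraries was set against 100 simulations of unchanged groups. Pseudogenes and genes with near-identical copies are named as uncertain, since reads may be split between copies. The test was run first on simulated counts of dispersion 0.0253 for the real genes, 200 of them changed. Of genes changed by a log2 fold change of size 1, it recovered 63.5% for mutant vehicle versus CD1 (17390 genes), 56.2% for mutant rapamycin versus mutant vehicle (17360 genes) and 53.1% for mutant rapamycin versus CD1 (17333 genes). Of those changed by size 2 it recovered 98%, 100% and 100%. It called 5 of 17196, 14 of 17166 and 8 of 17139 unchanged genes.

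The work used R 4.3.3 with limma 3.58.1 and the package data.table (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.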

Results

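Gene expression was measured by RNA sequencing in basal cells of the mouse prostate, the epithelial layer that lies against the basement membrane and is marked by Krt5, Krt14 and Trp63. The cells were isolated by fluorescence-activated cell sorting. The 6 libraries fell into 3 groups of 2. The first group came from CD1 mice, an outbred stock, and is labelled with ethanol. The second came from double mutant mice also given ethanol, the vehicle, and the third from double mutant mice given rapamycin, an inhibitor of the mTOR kinase, at 6 mg/kg. Per the genotype label, in the double mutants a Cre recombinase under the Krt5 promoter removed Pten, the phosphatase that opposes PI3 kinase, and switched on an activated form of Pik3ca, the catalytic subunit of that kinase. The series places the basal cell collection 3 weeks after these changes. The genotype label of the CD1 samples repeats that of the mutants, which contradicts their titles. Samples were grouped by title, and the data columns carry the name CD1 as well.

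The deposited values are reads per gene scaled to a common total, between 20012882 and 20015378 in every library. The reads behind them, as recovered from the values, numbered 16351366 and 15670144 in the CD1 libraries, 17299153 and 15100742 in the mutant vehicle libraries, and 18279236 and 13761287 in the mutant rapamycin libraries. Between 26617 and 28311 genes had a value above 0, and the 10 highest genes took between 5.46% and 7.18% of a library. All levels below are means ± SD of 2 libraries in these units, and all fold changes are on the log2(value + 1) scale, ± SE. This scale understates the change of genes with low values. No label says that the libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical. The first principal component held 60.4% of the variance and separated CD1 (scores −72.6 and −67.7) from mutant vehicle (89.4 and 59.1), with mutant rapamycin between them (2.7 and −11). The second (20.8%) separated mutant rapamycin (−45 and −52.6) from CD1 (32.1 and 22.9) and mutant vehicle (30.1 and 12.5).

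Pten (ENSMUSG00000013663, chromosome 19, 32757497 to 32826160, GRCm38) had 6548 ± 41 in CD1, 6953 ± 87.7 in mutant vehicle and 6168 ± 480 in mutant rapamycin. Neither mutant group differed from CD1 in limma's test (adjusted p = 0.572 and 0.664). The value is a whole-gene total that includes exons outside any deleted part, so it does not check the deletion. Pik3ca (ENSMUSG00000027665, chromosome 3, 32397671 to 32468486) had 3017 ± 165 in CD1, 2225 ± 113 in mutant vehicle and 3273 ± 59.4 in mutant rapamycin. Gt(ROSA)26Sor, the transcript of the Rosa26 locus that carries the reporter named in the genotype, was chosen after its values were seen. It had 387 ± 31.1 in CD1, 168 ± 75.7 in mutant vehicle and 121 ± 5.7 in mutant rapamycin, so that both mutant groups lay below CD1 (−1.28 ± 0.30, limma adjusted p = 0.0107, and −1.67 ± 0.30, limma adjusted p = 0.00949). It is annotated as antisense, and no source used here says whether the counting used strand.

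**Figure D1:**
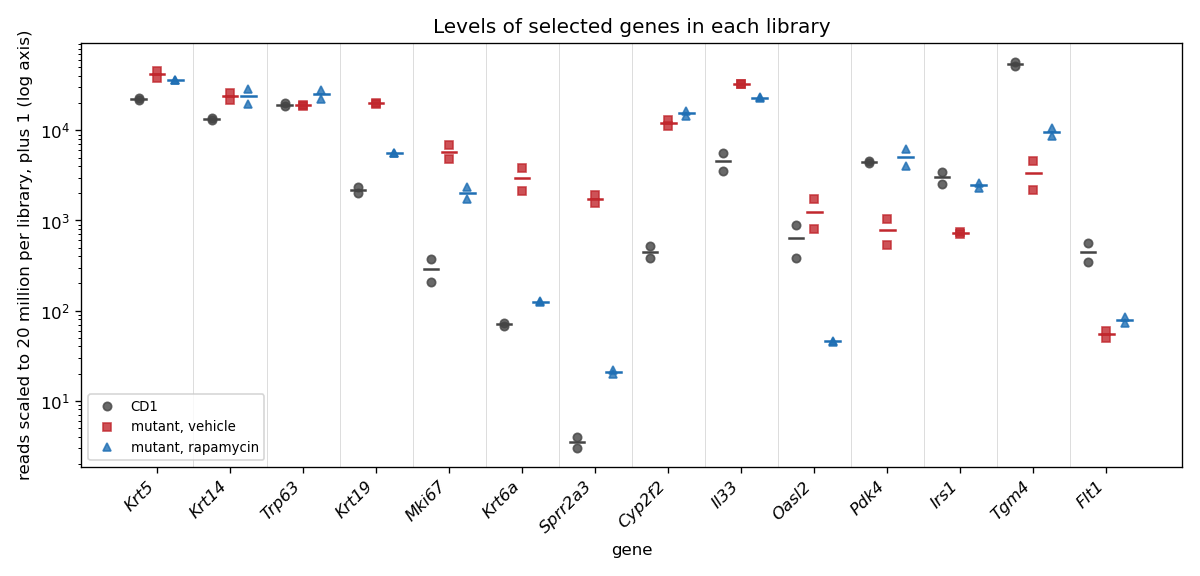
Levels of 14 named genes in each of the 6 libraries, as reads scaled to the common total plus 1 on a log axis, with points for libraries and horizontal bars for group means. Mki67, Krt6a and Sprr2a3 were highest in the mutant vehicle libraries, Oasl2 was lowest in the mutant rapamycin libraries, and Cyp2f2 was high in both mutant groups.

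The comparison of mutant vehicle with CD1 basal cells asks what changes in these cells once Pten is lost and Pik3ca is activated. Strain and genotype cannot be told apart in it. Of 40 cell cycle genes 33 rose, and of 23 squamous and wound genes 18: Mki67, a marker of cycling cells, had 5795 ± 1457 against 290 ± 118 in CD1, and Ivl, which encodes the envelope protein involucrin, had 575 ± 84.9 against 5 ± 2.8. Of 17 markers of proximal luminal progenitors 11 rose, with Cyp2f2 at 12155 ± 1446 against 446 ± 96.2. Of 28 target genes of the FoxO transcription factors 14 fell and 3 rose, among the former Irs2, an insulin receptor substrate, from 13562 ± 3245 to 2086 ± 662. Markers of secretory luminal, endothelial and stromal cells passed as lower lists. No list passed with an estimated correlation, a form with 3 residual degrees of freedom in which a pass was hard to reach. Of 17598 genes tested, 2741 rose and 2894 fell at an adjusted p under 0.05 in limma's test, and 1302 and 1802 of these changed at least 2-fold.

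Krt5 (ENSMUSG00000061527, chromosome 15, 101707070 to 101712898) rose from 22336 ± 923 to 42264 ± 5413 (0.91 ± 0.12, limma adjusted p = 0.000617), and Krt14 (ENSMUSG00000045545, chromosome 11, 100203162 to 100207548) from 13464 ± 529 to 23822 ± 2879 (0.82 ± 0.18, limma adjusted p = 0.0101). Trp63 (ENSMUSG00000022510, chromosome 16, 25683763 to 25892102), the transcription factor that maintains basal cells, had 18962 ± 222 against 19233 ± 1136 (limma adjusted p = 0.925). Among luminal keratin genes, Krt8 (ENSMUSG00000049382, chromosome 15, 101996698 to 102004482) had 6214 ± 487 against 4918 ± 65.1 (0.34 ± 0.13, limma adjusted p = 0.068), and Krt18 (ENSMUSG00000023043, chromosome 15, 102028180 to 102032027) fell from 6178 ± 558 to 3841 ± 680 (−0.69 ± 0.14). Of 24 basal identity genes, 10 rose and 5 fell, the same with p-values adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0595). Krt15 rose from 21203 ± 5068 to 70169 ± 277, and Col17a1, a hemidesmosome collagen gene, by 1.42 ± 0.12. In the CD1 libraries the secretory luminal marker gene Tgm4 lay above Krt5, Krt14 and Trp63. A larger share of luminal cells or their RNA in CD1 may therefore contribute to the rises of basal genes, which was not tested. Of 24 luminal identity genes, 9 rose and 6 fell, or 10 and 6 over the list alone (camera adjusted p = 0.321). Krt19 rose from 2187 ± 213 to 20002 ± 530, whereas Nkx3-1, a transcription factor of luminal cells, fell from 4461 ± 644 to 693 ± 346. The proximal luminal progenitor list passed as higher. Of its 17 tested genes 11 rose, and over the list alone 12 rose and 1 fell (median 1.83, camera adjusted p = 3.24e-06, adjusted p = 0.492 with an estimated correlation). Besides Cyp2f2 (4.78 ± 0.16), Krt4 rose from 580 ± 117 to 7116 ± 1665. The call of Krt14 ended without CD1 replicate 1 and also without mutant vehicle replicate 1.

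The 8 genes that rose most under the rule for named genes started close to or at 0 in CD1, so their levels are given in place of folds. Tmprss11g (chromosome 5), a membrane serine protease gene, was listed at 0 in both CD1 libraries and had 1283 ± 1054 in mutant vehicle. Wfdc18 (chromosome 11) had 964 ± 20.5 against 1 ± 1.4, and the desmosomal cadherin gene Dsg3 (chromosome 18) 1364 ± 1123 against 1.5 ± 2.1. Sprr2a3 (chromosome 3) and Ivl (chromosome 3), whose products build the cornified envelope of squamous epithelium, had 1744 ± 231 and 575 ± 84.9 against 2.5 ± 0.7 and 5 ± 2.8. Slc16a14 (chromosome 1) and Ms4a5 (chromosome 19) had 431 ± 155 and 221 ± 121 against 1.5 ± 2.1 and 1 ± 1.4. Rps2-ps13 (chromosome X), a pseudogene of Rps2, had 2926 ± 470 against 12.5 ± 6.4. Reads of Sprr2a3 and Rps2-ps13 may be shared with near-identical copies, and both are uncertain. The 8 genes that fell most were Ptprq (−5.18 ± 0.53, from 2107 ± 497 to 64.5 ± 44.5), Gsdma (−5.00 ± 0.27), Lamc3 (−4.95 ± 0.36), C1rb (−4.70 ± 0.42), Azgp1 (−4.46 ± 0.71), Pde3a (−4.40 ± 0.42), Cyp26b1 (−4.16 ± 0.30) and Bglap3 (−4.14 ± 0.34). The call of Tmprss11g ended with either CD1 library left out, although both listed it at 0. Calls also ended, with highest limma adjusted p = 0.134 for Tmprss11g, 0.106 for Dsg3, 0.0996 for Ms4a5 and 0.0934 for Azgp1 (voom).

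Proliferation and squamous genes gave the lowest p-values of the 34 lists tested. Of 40 cell cycle genes, 33 rose, and 36 over the list alone (median 2.36, camera adjusted p = 3.66e-14, adjusted p = 0.492 with an estimated correlation). Mki67 rose by 4.36 ± 0.34 and Top2a, which untangles replicated DNA, by 3.98 ± 0.73. Of 23 squamous and wound genes, 18 rose, and 19 over the list alone (median 2.93, camera adjusted p = 9.61e-12, adjusted p = 0.492 with an estimated correlation). Anxa8 rose by 6.49 ± 0.48, from 32.5 ± 14.8 to 3124 ± 1800, and Dsg3 and Ivl are named above. The p53 and senescence list passed as higher, with 7 of 21 genes up and 2 down, or 9 and 2 over the list alone (median 0.46, camera adjusted p = 0.0141, adjusted p = 0.492 with an estimated correlation). In it Ckap2 (3.39 ± 0.52), a spindle protein gene, and Lmnb1 (1.12 ± 0.17), a lamin gene, rose, while Btg2, an antiproliferative gene, fell (−1.14 ± 0.20). With such members the pass of the list does not by itself show p53 activity or senescence. This list did not pass without CD1 replicate 1 (median 0.34, camera adjusted p = 0.092) or with the stricter filter (median 0.48, camera adjusted p = 0.0508). Calls that ended when 1 library was left out had limma adjusted p = 0.142 for Top2a without mutant vehicle replicate 1, and 0.0795 for Top2a without mutant vehicle replicate 2. Other settings ended calls, with highest limma adjusted p = 0.0636 for Top2a (no filter, block).

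Several metabolic and biosynthetic lists passed as higher, but not cholesterol or fatty acid synthesis or ATF4 targets. Of 22 glycolysis genes 12 rose and 1 fell, the same over the list alone (median 0.74, camera adjusted p = 0.000118, adjusted p = 0.492 with an estimated correlation). Pkm, which makes pyruvate, rose from 4197 ± 560 to 13628 ± 3081, and the member that fell was Pfkfb3 (−1.64 ± 0.15), which makes an activator of glycolysis. Of 16 pentose phosphate and NADPH genes 10 rose and 1 fell, the same over the list alone (median 0.86, camera adjusted p = 0.000369, adjusted p = 0.492 with an estimated correlation). Idh1 rose by 1.86 ± 0.13 and G6pdx, the first enzyme of the pathway, by 1.35 ± 0.17. Of 79 oxidative phosphorylation genes 37 rose and 3 fell, or 45 and 4 over the list alone (median 0.46, camera adjusted p = 7.6e-08, adjusted p = 0.593 with an estimated correlation). Ndufc2 and Atp5g3 rose by 1.05 ± 0.17 and 0.87 ± 0.18. Of 36 ribosome biogenesis and MYC target genes 17 rose and 1 fell, or 25 and 2 over the list alone (median 0.61, camera adjusted p = 2.65e-05, adjusted p = 0.608 with an estimated correlation). Bop1 and Srm rose by 1.24 ± 0.21 and 1.22 ± 0.31, and the member that fell was Myc itself (−0.72). Of 85 cytosolic ribosomal protein genes 13 rose and 1 fell, or 8 and 1 over the list alone (median 0.17, camera adjusted p = 0.00138, adjusted p = 0.721 with an estimated correlation). Rpl34 and Rpsa rose by 1.15 ± 0.15 and 0.94 ± 0.12, and both share sequence with pseudogenes. Without mutant vehicle replicate 1 the ribosomal protein list did not pass (median 0.1, camera adjusted p = 0.0643), and the ribosome biogenesis median was 0.33. The call of Srm ended without CD1 replicate 1 and also without mutant vehicle replicate 1.

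Of the immune lists, 4 passed as higher, with a wide gap between the mutant vehicle libraries. Of 38 interferon response genes 8 rose and 1 fell, or 5 and 1 over the list alone (median 1.71, camera adjusted p = 1.58e-05, adjusted p = 0.608 with an estimated correlation). The list median relative to CD1 was 2.67 in mutant vehicle replicate 1, 0.78 in replicate 2, and 0.52 and −0.52 in the CD1 libraries. The list median was 0.75 without mutant vehicle replicate 1. Oas3 and Oas2, sensors of double-stranded RNA, had 258 ± 238 and 151 ± 149 against 5 ± 4.2 and 8 ± 8.5. Of 26 innate immune and antimicrobial genes 7 rose and 3 fell, or 9 and 3 over the list alone (median 0.58, camera adjusted p = 0.0185, adjusted p = 0.608 with an estimated correlation). The alarmin Il33 rose from 4563 ± 1441 to 32889 ± 174, and Reg3g had 394 ± 321 against 3.5 ± 2.1. Of 30 chemokine and cytokine genes 6 rose and 4 fell, the same over the list alone (median 0.5, camera adjusted p = 0.0374, adjusted p = 0.608 with an estimated correlation). Cxcl5 had 656 ± 842 against 3 ± 0, and Tnfsf10 1327 ± 1205 against 67.5 ± 41.7. Of 21 MHC class I genes 5 rose, also over the list alone (median 0.46, camera adjusted p = 0.0324, adjusted p = 0.693 with an estimated correlation). Psmb8 and Psme2 rose by 1.70 ± 0.49 and 1.45 ± 0.25. Of the rest, 1 of 21 immune cell markers rose (median 0.71, camera adjusted p = 0.141), and over the list alone the call did not hold. Without mutant vehicle replicate 1 the innate immune, chemokine and MHC class I lists did not pass (medians 0.11, 0.2 and 0.09, camera adjusted p = 0.234, 0.371 and 0.461), nor did they with the stricter filter (medians 0.65, 0.41 and 0.35, camera adjusted p = 0.116, 0.178 and 0.162), and without replicate 2 their medians were 1.18, 0.92 and 0.93. With no filter the innate immune median was 0.9. The chemokine list also did not pass without CD1 replicate 1 (camera adjusted p = 0.0701) or with either other scaling (median of ratios, camera adjusted p = 0.0632), and the MHC class I list without CD1 replicate 1 or 2 (camera adjusted p = 0.0567 and 0.0669). With CD1 replicate 2 left out, the calls of Oas2, Cxcl5, Tnfsf10 and Psmb8 ended. With CD1 replicate 1 left out, those of Cxcl5, Tnfsf10 and Psmb8 ended. Leaving out mutant rapamycin replicate 2, outside this comparison, ended those of Oas2, Cxcl5 and Psmb8. Leaving out mutant rapamycin replicate 1 ended those of Cxcl5 and Psmb8, and leaving out mutant vehicle replicate 1 that of Psmb8. Calls also ended, with highest limma adjusted p = 0.0921 for Oas3 and 0.0527 for Reg3g (voom), 0.14 for Oas2 (voom, no filter, only 4 libraries, pseudocount 0.1), 0.375 for Cxcl5 and 0.118 for Tnfsf10 (voom, no filter, only 4 libraries), and 0.0886 for Psmb8 (voom, only 4 libraries).

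NF-kB signalling is named in the title of the series. Of 31 NF-kB target genes 6 rose and 6 fell, the same over the list alone, and the list did not pass (camera adjusted p = 0.925). Its median and mean were 0.11 and 0.56 while the test pointed down. Tnf rose from 30 ± 11.3 to 160 ± 81.3 and Ptgs2 from 201 ± 79.9 to 1419 ± 1090, whereas Map3k8 fell from 567 ± 132 to 156 ± 16.3. Nfkbia (ENSMUSG00000021025, chromosome 12, 55489410 to 55492647), the inhibitor that NF-kB itself induces, had 5454 ± 233 against 6655 ± 1312 (limma adjusted p = 0.185). Tnfaip3 (ENSMUSG00000019850, chromosome 10, 19000910 to 19015657), which ends the signal, rose from 2601 ± 858 to 4486 ± 366 (limma adjusted p = 0.0262). Calls that ended when 1 library was left out had limma adjusted p = 0.224 for Ptgs2 and 0.0727 for Tnfaip3 without CD1 replicate 1, 0.133 for Ptgs2 without CD1 replicate 2, 0.0765 for Ptgs2 without mutant rapamycin replicate 1, 0.0769 for Ptgs2 without mutant rapamycin replicate 2, 0.15 for Tnfaip3 without mutant vehicle replicate 1, and 0.0686 for Tnfaip3 without mutant vehicle replicate 2. Other settings ended calls, with highest limma adjusted p = 0.122 for Ptgs2 (voom, no filter, only 4 libraries, block), and 0.0551 for Tnfaip3 (both other scalings).

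Of 28 FoxO target genes 14 fell and 3 rose, or 17 and 3 over the list alone (median −0.63, camera adjusted p = 6.16e-05, adjusted p = 0.492 with an estimated correlation). Irs2 and Pdk4, the latter a brake on pyruvate oxidation, fell (−2.72 ± 0.30 and −2.59 ± 0.36). Of 19 EGFR pathway genes 10 fell and 2 rose, or 11 and 2 over the list alone (median −0.62, camera adjusted p = 0.00247, adjusted p = 0.492 with an estimated correlation). The receptor gene Erbb4 fell (−3.66 ± 0.31), and the ligand gene Areg rose (3.65 ± 0.69). Of 28 dissociation and immediate early genes 11 fell and 1 rose, the same over the list alone (median −0.51, camera adjusted p = 0.000117, adjusted p = 0.492 with an estimated correlation). Junb and Maff fell (−1.29 ± 0.14 and −1.63 ± 0.30). Of 18 secretory luminal markers 11 fell, and 13 over the list alone (median −2.35, camera adjusted p = 1.75e-08, adjusted p = 0.492 with an estimated correlation). Tgm4, a secreted transglutaminase of the prostate, fell from 54666 ± 3396 to 3406 ± 1703. Of 14 endothelial markers 12 fell, and over the list alone 13 fell and 1 rose (median −2.01, camera adjusted p = 2.2e-05, adjusted p = 0.579 with an estimated correlation). Flt1, a VEGF receptor gene, fell from 451 ± 153 to 54 ± 7.1. Of 20 stromal and smooth muscle markers 9 fell and 3 rose, or 12 and 3 over the list alone (median −1.17, camera adjusted p = 0.00594, adjusted p = 0.492 with an estimated correlation). Pdgfra fell from 933 ± 306 to 126 ± 43.8, and Thy1 rose (1.71). The endothelial median was −1.31 without CD1 replicate 1, and that of dissociation genes −0.33 without mutant vehicle replicate 1. The call of Maff ended with either CD1 library left out.

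The other lists did not pass in camera. Rising and falling genes numbered 2 and 0 of 25 in cholesterol synthesis (over the list alone 0 and 0), 6 and 5 of 21 in fatty acid synthesis (8 and 6), 10 and 9 of 32 among ATF4 targets (10 and 12), and 9 and 8 of 38 in lysosome and autophagy (9 and 13). They numbered 2 and 5 of 16 in IL-17 signalling (2 and 5), 4 and 7 of 23 in JAK-STAT3 signalling (4 and 7), 7 and 5 of 22 in the hypoxia response (7 and 6), and 8 and 5 of 25 in the EMT and matrix list (9 and 5). They numbered 3 and 4 of 31 PI3K and mTOR components (3 and 4), 6 and 12 of 32 Notch, Wnt and Hedgehog genes (6 and 13), and 2 and 0 of 14 mitochondrially encoded transcripts (0 and 0). The camera adjusted p of these lists lay between 0.0746 and 0.896. The median or mean and the test differed in sign for fatty acid synthesis, lysosome and autophagy, and IL-17 signalling. Too few genes for a test were left of the neuroendocrine and glial list (2 of 4 fell), the seminal vesicle and urethral list (2 of 4 rose and 2 fell) and the red blood cell list (its 1 gene did not pass). With a library left out, some lists passed: basal identity (medians 0.23 and 0.28), cholesterol synthesis (0.69 and 0.53) and EMT and matrix (0.56 and 0.76) without CD1 replicate 2 or mutant vehicle replicate 2, immune cell markers (0.88) without mutant vehicle replicate 2, mitochondrial transcripts (0.49 and 0.34) without CD1 replicate 2 or mutant vehicle replicate 1, and JAK-STAT3 signalling as lower (−0.37 and −0.62) without CD1 replicate 1 or mutant vehicle replicate 1. With no filter basal identity, cholesterol synthesis, EMT and mitochondrial transcripts passed (0.2, 0.25, 0.49 and 0.3).

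Leaving out mutant vehicle replicate 1 reduced the counts to 1335 up and 1703 down, leaving out CD1 replicate 1 to 1817 and 1500, and leaving out CD1 replicate 2 to 1800 and 1930. Of 133 genes named in this comparison by the rule and past the threshold, 31 lost the call when some library was left out, and in each of these the direction was the same. Under alternatives that left out no library 21 lost it, 15 of them with voom.

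The comparison of mutant rapamycin with mutant vehicle asks what rapamycin changes in the double mutant cells. With rapamycin 10 of 23 squamous, 12 of 17 proximal luminal and 18 of 38 interferon genes fell: Krt6a had 125 ± 2.1 against 2954 ± 1194, Clu, a stress-induced chaperone gene, 747 ± 298 against 7368 ± 507, and the interferon-induced gene Oasl2 44.5 ± 0.7 against 1255 ± 648. So did 11 of 25 cholesterol synthesis, 13 of 22 glycolysis and 15 of 40 cell cycle genes. Of 28 FoxO target genes 12 rose, with Pdk4 at 5109 ± 1479 against 787 ± 356. No list passed with an estimated correlation, on 3 residual degrees of freedom. In limma's test 982 genes rose and 1505 fell at an adjusted p under 0.05, and 440 and 814 of these changed at least 2-fold. With trimmed-mean scaling in place of the deposited one, 1168 rose and 1180 fell, so the share of rising genes moved from 39.5% to 49.7%.

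Among the fixed genes, Krt8 fell from 6214 ± 487 to 4486 ± 594 (−0.47 ± 0.13, limma adjusted p = 0.0364), Nfkbia rose from 5454 ± 233 to 7890 ± 842 (0.53 ± 0.15, limma adjusted p = 0.0433), and Pik3ca rose (0.56 ± 0.11, limma adjusted p = 0.0144). Krt5 had 35936 ± 26.2 against 42264 ± 5413 (limma adjusted p = 0.227), Krt14 24148 ± 6472 against 23822 ± 2879 (limma adjusted p = 0.997), and Trp63 25317 ± 3889 against 18962 ± 222 (limma adjusted p = 0.0611). Krt18, Tnfaip3 and Pten did not pass either, with differences of 0.34 ± 0.14, −0.04 ± 0.22 and −0.18 ± 0.11 and limma adjusted p = 0.146, 0.917 and 0.301. The 8 genes that rose most were led by Klk1b22 (chromosome 7), listed at 0 in both vehicle libraries and at 317 ± 79.9 with rapamycin. This kallikrein gene and the pseudogene Rpl17-ps5 (3.19 ± 0.47) have near-identical copies and are uncertain. The others were Ptprq (3.17 ± 0.53), Mdga2 (2.91 ± 0.36), Bmp4 (2.90 ± 0.37), Pdk4 (2.74 ± 0.36), Cyp26b1 (2.64 ± 0.30) and Rgs16 (2.62 ± 0.29). The 8 that fell most were Dsg3 (to 11 ± 7.1), Nos1 (1004 ± 631 to 10 ± 5.7), Wfdc18 (to 10.5 ± 3.5), Sprr2a3 (to 20 ± 1.4), Rsad2 (798 ± 854 to 10 ± 9.9), Gabrp (806 ± 204 to 18.5 ± 14.8), Tnfsf10 (to 29.5 ± 10.6) and Nupr1 (682 ± 84.1 to 20 ± 9.9). With mutant rapamycin replicate 1 left out, the calls of Krt8, Nfkbia, Pik3ca, Ptprq, Nos1, Rsad2, Gabrp and Tnfsf10 ended. With mutant rapamycin replicate 2 left out, the same calls and those of Rpl17-ps5 and Dsg3 ended. Leaving out mutant vehicle replicate 1 ended those of Krt8, Nfkbia, Pik3ca, Nos1 and Gabrp. Leaving out mutant vehicle replicate 2 ended those of Krt8, Nfkbia and Gabrp. The call of Rsad2 also ended with either CD1 library left out, and that of Tnfsf10 without CD1 replicate 2. The CD1 libraries are outside this comparison. Calls also ended, with highest limma adjusted p = 0.112 for Krt8 (only 4 libraries, both other scalings), 0.0713 for Nfkbia (both other scalings, not robust), 0.0502 for Ptprq and 0.113 for Gabrp (no filter), 0.127 for Dsg3 (voom, pseudocount 0.1), 0.0664 for Nos1 (voom, no filter), and 0.269 for Rsad2 and 0.163 for Tnfsf10 (voom, no filter, only 4 libraries).

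Interferon genes gave the lowest p-value among the lists. Of 38 tested, 18 fell, and 25 over the list alone (median −3.18, camera adjusted p = 1.93e-13, adjusted p = 0.476 with an estimated correlation). The median relative to CD1 was −0.94 and −1.14 in the rapamycin libraries, and without mutant vehicle replicate 1 the change was −1.63. Oas3 fell to 3.5 ± 2.1, and Oasl2 fell (−4.68 ± 0.51). Of 26 innate immune and antimicrobial genes 7 fell, and 9 over the list alone (median −1.31, camera adjusted p = 1.04e-05, adjusted p = 0.476 with an estimated correlation). Il1rn, the interleukin-1 receptor antagonist gene, fell from 369 ± 223 to 18.5 ± 3.5 and Reg3g to 27 ± 2.8. Of 21 MHC class I genes 8 fell, and 13 over the list alone (median −0.74, camera adjusted p = 1.83e-06, adjusted p = 0.476 with an estimated correlation). Psmb8 and Psmb9, subunits of the immunoproteasome, fell (−2.26 ± 0.49 and −1.62 ± 0.41). Immune cell markers passed as lower, with 3 of 21 genes down, the same over the list alone (median −1.16, camera adjusted p = 0.000174, adjusted p = 0.476 with an estimated correlation). Laptm5 and Cd53 fell from 88 ± 17 and 44.5 ± 13.4 to 24.5 ± 7.8 and 11 ± 4.2, all low levels. The immune cell list did not pass with the stricter filter (camera adjusted p = 0.0666). Without mutant vehicle replicate 1 the innate immune and MHC class I medians were −0.66 and −0.48, and without replicate 2 the latter was −1.2. Calls that ended when 1 library was left out had limma adjusted p = 0.0556 for Oas3, 0.0588 for Reg3g, 0.0865 for Psmb8, 0.106 for Psmb9 and 0.0628 for Cd53 without mutant rapamycin replicate 1, 0.052 for Oas3, 0.0656 for Oasl2, 0.0985 for Reg3g, 0.166 for Psmb8, 0.169 for Psmb9, 0.102 for Laptm5 and 0.197 for Cd53 without mutant rapamycin replicate 2, and 0.0609 for Psmb8, 0.219 for Psmb9, 0.0974 for Laptm5 and 0.238 for Cd53 without mutant vehicle replicate 1. Other settings ended calls, with highest limma adjusted p = 0.137 for Oas3, 0.0985 for Reg3g, 0.0844 for Psmb8 and 0.0606 for Psmb9 (voom).

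The NF-kB target list did not pass, with 4 genes up and 4 down of 31, the same over the list alone (median −0.13, camera adjusted p = 0.532). Il1a fell from 121 ± 48.1 to 24 ± 1.4 and Tnf to 37 ± 9.9, while Il6 rose (1.21). Without mutant vehicle replicate 2 the list passed as lower (median −0.17, camera adjusted p = 0.00511). Of 30 chemokine and cytokine genes 3 rose and 4 fell, the same over the list alone (camera adjusted p = 0.249), and this list also passed as lower without mutant vehicle replicate 2 (median −1.31, camera adjusted p = 0.00207) and without mutant rapamycin replicate 2 (median −0.67). The call of Tnf ended with either mutant rapamycin library left out and also without mutant vehicle replicate 1.

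Some epithelial lists passed as lower, and the basal list did not. Of 17 proximal luminal progenitor genes 12 fell, and over the list alone 13 fell and 1 rose (median −2.11, camera adjusted p = 4.54e-08, adjusted p = 0.476 with an estimated correlation). Lgals3 fell from 1370 ± 7.1 to 89 ± 2.8 and Clu (−3.36 ± 0.30), while Cyp2f2 had 15471 ± 1489 against 12155 ± 1446 and did not pass (limma adjusted p = 0.182). Of 24 luminal identity genes 11 fell and 2 rose, or 12 and 2 over the list alone (median −0.63, camera adjusted p = 0.000656, adjusted p = 0.476 with an estimated correlation). Tspan8 and Cldn7, a tight junction gene, fell (−3.27 ± 0.36 and −2.72 ± 0.25), whereas Nkx3-1 rose (1.70). Of 23 squamous and wound genes 10 fell, and over the list alone 11 fell and 2 rose (median −1.22, camera adjusted p = 2.77e-06, adjusted p = 0.476 with an estimated correlation). Krt6a and Ivl fell (−4.50 ± 0.26 and −4.33 ± 0.39). Basal identity genes did not pass, with 5 up and 3 down of 24, or 6 and 4 over the list alone (camera adjusted p = 0.263), and their median of 0.05 and mean of −0.04 differ in sign. Of 40 cell cycle genes 15 fell and 1 rose, or 27 and 1 over the list alone (median −1.52, camera adjusted p = 1.06e-09, adjusted p = 0.476 with an estimated correlation). Ube2c and Plk1, which act in mitosis, fell (−2.18 ± 0.48 and −2.10 ± 0.48), and Mki67 fell to 2027 ± 433. The squamous median was −0.6 without mutant vehicle replicate 1. The call of Nkx3-1 ended with either mutant rapamycin library left out, and with either CD1 library, which are outside this comparison. The call of Ube2c ended with any library of either mutant group left out. That of Plk1 ended without mutant rapamycin replicate 2 and also without mutant vehicle replicate 1. Calls also ended, with highest limma adjusted p = 0.0998 for Nkx3-1 (no filter, only 4 libraries, block), and 0.0542 for Ube2c (block).

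Some metabolic lists passed as lower, but not fatty acid synthesis, and FoxO targets as higher. Of 25 cholesterol synthesis genes 11 fell, and 19 over the list alone (median −0.91, camera adjusted p = 1.3e-08, adjusted p = 0.476 with an estimated correlation). Fdps and Dhcr24 fell (−2.15 ± 0.34 and −2.04 ± 0.28). Of 22 glycolysis genes 13 fell and 1 rose, or 14 and 1 over the list alone (median −0.83, camera adjusted p = 2.34e-05, adjusted p = 0.476 with an estimated correlation). The lactate transporter gene Slc16a3 and Pkm fell (−1.94 ± 0.26 and −1.42 ± 0.16). Of 16 pentose phosphate and NADPH genes 5 fell, and 8 over the list alone (median −0.4, camera adjusted p = 0.00478, adjusted p = 0.476 with an estimated correlation). G6pdx fell (−1.48 ± 0.17). Of 36 ribosome biogenesis and MYC target genes 14 fell and 1 rose, or 26 and 1 over the list alone (median −0.67, camera adjusted p = 2.67e-07, adjusted p = 0.552 with an estimated correlation). Srm fell (−1.66 ± 0.31), and the member that rose was Myc (0.96 ± 0.20). Of 79 oxidative phosphorylation genes 17 fell and 1 rose, or 27 and 1 over the list alone (median −0.36, camera adjusted p = 9.6e-07, adjusted p = 0.571 with an estimated correlation). Atp5g1 fell (−0.80 ± 0.19). Of 28 FoxO target genes 12 rose, and over the list alone 15 rose and 1 fell (median 0.52, camera adjusted p = 5.51e-08, adjusted p = 0.476 with an estimated correlation). Irs2 and Irs1 rose by 1.84 ± 0.30 and 1.76 ± 0.16. Of 19 EGFR pathway genes 6 rose and 1 fell, or 10 and 2 over the list alone (median 0.51, camera adjusted p = 0.00217, adjusted p = 0.476 with an estimated correlation). Spry4, a feedback inhibitor of receptor signalling, rose by 1.80 ± 0.27. Of 32 Notch, Wnt and Hedgehog genes 5 rose and 1 fell, or 8 and 1 over the list alone (median 0.3, camera adjusted p = 0.00412, adjusted p = 0.476 with an estimated correlation). The Wnt feedback genes Nkd1 and Axin2 rose by 1.73 ± 0.30 and 1.24 ± 0.20, and Notch3 fell (−1.92). Of 28 dissociation and immediate early genes 8 rose, and over the list alone 9 rose and 1 fell (median 0.41, camera adjusted p = 2.83e-05, adjusted p = 0.476 with an estimated correlation). Maff and Klf4 rose by 1.29 ± 0.30 and 0.87 ± 0.21. The pentose phosphate list did not pass without mutant rapamycin replicate 1 (median −0.48, camera adjusted p = 0.119), nor the EGFR list without mutant rapamycin replicate 2 (median 0.31, camera adjusted p = 0.0957). The medians of ribosome biogenesis and dissociation genes were −0.4 and 0.22 without mutant vehicle replicate 1, and without replicate 2 that of the Notch list was 0.16. Calls that ended when 1 library was left out had limma adjusted p = 0.0787 for Fdps, 0.0605 for Dhcr24, 0.0992 for Srm, 0.125 for Myc, 0.149 for Atp5g1, 0.0889 for Irs2, 0.0629 for Nkd1, 0.0604 for Axin2, 0.195 for Notch3, 0.162 for Maff and 0.099 for Klf4 without mutant rapamycin replicate 2, 0.0707 for Srm, 0.166 for Myc, 0.104 for Atp5g1, 0.0532 for Irs2, 0.197 for Notch3, 0.0888 for Maff and 0.214 for Klf4 without mutant vehicle replicate 1, 0.09 for Atp5g1 and 0.0644 for Klf4 without mutant vehicle replicate 2, 0.0512 for Axin2 and 0.106 for Notch3 without mutant rapamycin replicate 1, 0.0902 for Maff and 0.052 for Klf4 without CD1 replicate 1, and 0.0922 for Maff and 0.0522 for Klf4 without CD1 replicate 2. Other settings ended calls, with highest limma adjusted p = 0.0576 for Irs2 (no filter), 0.0791 for Notch3 (voom), 0.129 for Maff (no filter, only 4 libraries), and 0.0522 for Klf4 (only 4 libraries).

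Endothelial, stromal and secretory luminal markers did not pass as lists between the mutant groups. Of 14 endothelial markers 0 passed in limma's test, 1 had an unadjusted p under 0.05 and 0 passed with voom (median 0.13, camera adjusted p = 0.489). Stromal markers numbered 2 up and 1 down of 20, the same over the list alone (camera adjusted p = 0.489, with a median of −0.12 against an upward test), and secretory luminal markers 2 up and 1 down of 18, or 5 and 2 over the list alone (camera adjusted p = 0.139). Secretory luminal markers passed as higher without mutant vehicle replicate 2 (median 0.87, camera adjusted p = 0.000112). The other lists that did not pass were IL-17 signalling (2 up and 0 down of 16), JAK-STAT3 signalling (5 and 4 of 23), fatty acid synthesis (2 and 7 of 21, or 3 and 10 over the list alone), ATF4 targets (5 and 7 of 32, or 5 and 10) and lysosome and autophagy (2 and 8 of 38, or 2 and 9). They further were cytosolic ribosomal proteins (0 and 3 of 85, or 0 and 0), p53 and senescence (0 and 1 of 21, or 0 and 0), hypoxia (2 and 3 of 22, or 2 and 5), EMT and matrix (3 and 4 of 25, or 4 and 5) and PI3K and mTOR components (2 and 2 of 31). Of 14 mitochondrially encoded transcripts 0 passed with limma or voom, and 0 had an unadjusted p under 0.05. The camera adjusted p of these lists lay between 0.2 and 0.865, and the median or mean and the test differed in sign for IL-17 signalling, JAK-STAT3 signalling, cytosolic ribosomal proteins and PI3K and mTOR components. Of the lists too small to test, the seminal vesicle and urethral list had 1 gene up and 2 down of 4, and the other 2 had 0 called genes with limma or voom and 0 at an unadjusted p under 0.05. Lists that passed as higher with a library left out were IL-17 and JAK-STAT3 signalling (medians 0.15 and 0.46) without mutant vehicle replicate 1, and cytosolic ribosomal proteins (0.07 and 0.04) without mutant vehicle replicate 1 or mutant rapamycin replicate 1.

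**Figure D2:**
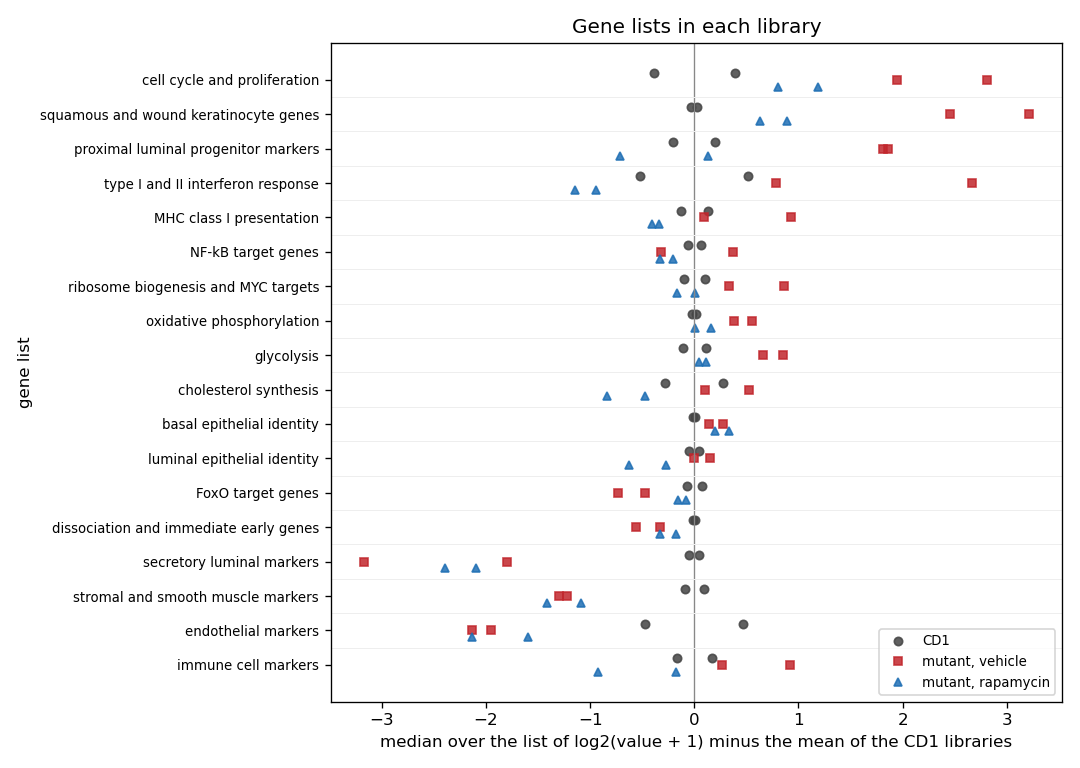
Medians of 18 gene lists in each of the 6 libraries, as the median over the list of log2(value + 1) minus the mean of the CD1 libraries, with a point for each library. The interferon list sat at 2.67 and 0.78 in the mutant vehicle libraries and at −0.94 and −1.14 in the mutant rapamycin libraries, whereas the endothelial list lay between −1.6 and −2.13 in the 4 mutant libraries.

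Fewer genes passed in this comparison without mutant rapamycin replicate 2, without mutant vehicle replicate 1 or without mutant rapamycin replicate 1. Fewer libraries alone also lower such counts. Of 123 genes named by the rule and past the threshold, 82 lost the call when some library was left out, 80 of them without mutant rapamycin replicate 2, and in each of these the direction was the same. Under alternatives that left out no library 36 lost it, 16 of them with voom.

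The overlap of both comparisons asks how far rapamycin moves the genes that differ between mutant vehicle and CD1 cells. Of the 2741 genes higher in mutant vehicle, 1114 fell with rapamycin, among them Krt6a, Sprr2a3, Lgals3 and Pkm. Of the 2894 lower genes, 801 rose with rapamycin, among them Irs1, Pdk4, Axin2 and Cyp26b1. With median-of-ratios scaling these overlaps were 891 and 925 genes, and with trimmed means 904 and 920, so which of them was larger depended on the scaling. Both comparisons share the mutant vehicle libraries, which pushes their fold changes in opposite directions with no effect at all. In 100 simulations of unchanged groups the overlaps averaged 0.41 and 0.28, and independent lists of these sizes would share 234.4 and 161.5 genes. Hardly any gene is called in unchanged groups, so the simulated overlaps do not size the part due to sharing. The 2 shared libraries are too few to split into sets of 2, so part of the excess in these counts may come from sharing them. Across genes, which are not independent replicates, the fold changes correlated at −0.73, against −0.5 in the simulations. Their covariance was −0.626 against −0.057, a difference of −0.57. In the same direction in both comparisons lay 6 rising genes (Prokr2, Adamts9, Bnc2, Nectin3, Cbs and A930011G23Rik) and 16 falling genes. These were named after their values were seen. Cbs, which encodes an enzyme of the pathway to cysteine, had 1983 ± 367 in CD1, 3152 ± 837 in mutant vehicle and 5270 ± 93.3 in mutant rapamycin.

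The shared libraries were removed by holding out each mutant vehicle library in turn. Genes were called with the other vehicle library, and their response to rapamycin was measured against the held-out library alone, as a value with no test. Genes that rose had a median response of −0.75 with library 1 held out and −0.49 with library 2 held out, and 89.4% and 92.8% of them were lower with rapamycin. Genes that fell had a median response of 0.75 and 0.41, and 89.1% and 81.1% of them were higher. The median of all genes was −0.06 and −0.08. The overlaps were 251 and 275 genes without mutant vehicle replicate 1, 297 and 204 without mutant rapamycin replicate 2, and 716 and 375 without mutant rapamycin replicate 1.

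The comparison of mutant rapamycin with CD1 asks what still differs from CD1 basal cells after rapamycin. Of 17 proximal luminal progenitor markers 4 rose, Cyp2f2 to 15471 ± 1489 against 446 ± 96.2 in CD1, and 4 fell, and the list did not pass (camera adjusted p = 0.826). Of 40 cell cycle genes 6 rose, with Mki67 at 2027 ± 433 against 290 ± 118. Of 24 basal identity genes 8 rose, with Krt5 and Krt15 at 35936 ± 26.2 and 61012 ± 2251 against 22336 ± 923 and 21203 ± 5068. Lower than in CD1 were 6 of 25 cholesterol synthesis and 3 of 38 interferon genes, and 8 of 18 secretory, 10 of 14 endothelial and 9 of 20 stromal markers. No list passed with an estimated correlation, on 3 residual degrees of freedom. In limma's test 693 genes rose and 1144 fell, and 378 and 811 of these changed at least 2-fold. With trimmed-mean scaling 878 rose and 907 fell, so the share of rising genes moved from 37.7% to 49.2%.

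The 8 genes that rose most were Ms4a5 (361 ± 300, against 1 ± 1.4 in CD1), Rps2-ps13 (2004 ± 50.9), Klk1b22 (against 2 ± 2.8 in CD1), Cyp2f2 (5.13 ± 0.16), Cck (4.92 ± 0.36), Il1r2 (4.83 ± 0.55), Gdpd2 (4.72 ± 0.25) and Gjb6 (4.57 ± 0.30). Il1r2 encodes the decoy receptor of interleukin-1. The 8 that fell most were Azgp1 (−5.03 ± 0.71), Bglap3 (−4.04 ± 0.34), Oasl2 (−3.68 ± 0.51), Psca (−3.52 ± 0.36), Fut2 (−3.36 ± 0.25), Rps24-ps3 (−3.36 ± 0.19), Adhfe1 (−3.24 ± 0.58) and Fmo3 (−3.23 ± 0.54). The pseudogenes are uncertain. Krt5 and Krt14 rose by 0.69 ± 0.12 and 0.82 ± 0.18 (limma adjusted p = 0.00798 and 0.0265). Trp63, Krt8, Krt18, Pik3ca, Nfkbia and Tnfaip3 did not pass, with differences of 0.39, −0.14, −0.36, 0.12, 0.26 and 0.78. With CD1 replicate 1 left out, the calls of Ms4a5, Il1r2, Adhfe1, Fmo3, Krt5 and Krt14 ended. With CD1 replicate 2 left out, those of Il1r2, Fmo3 and Krt14 ended. Leaving out mutant rapamycin replicate 2 ended those of Azgp1, Oasl2, Adhfe1, Fmo3, Krt5 and Krt14. Leaving out mutant rapamycin replicate 1 ended those of Oasl2, Fmo3 and Krt5. Calls also ended, with highest limma adjusted p = 0.155 for Ms4a5, 0.0644 for Il1r2, 0.164 for Azgp1 and 0.102 for Oasl2 (voom), and 0.0751 for Fmo3 and 0.0547 for Krt14 (no filter).

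Of 34 lists, 9 passed as higher and 7 as lower. Basal identity genes passed as higher, with 8 of 24 up, and 9 over the list alone (median 0.29, camera adjusted p = 1.19e-06, adjusted p = 0.354 with an estimated correlation). Krt15 rose by 1.55 ± 0.15 and Col17a1 by 0.95 ± 0.12. Luminal cells or their RNA in the CD1 libraries may contribute to these rises too, which was not tested. Of 23 squamous and wound genes 8 rose, and over the list alone 13 rose and 1 fell (median 0.8, camera adjusted p = 5.04e-10, adjusted p = 0.671 with an estimated correlation). Gjb6 and Anxa8 had 265 ± 72.1 and 293 ± 21.2 against 10 ± 1.4 and 32.5 ± 14.8. Of 40 cell cycle genes 6 rose, and 12 over the list alone (median 0.96, camera adjusted p = 5.04e-10, adjusted p = 0.742 with an estimated correlation). Mki67 rose by 2.85 ± 0.34 and Foxm1 by 1.60 ± 0.31. The pentose phosphate list passed with 3 up and 1 down of 16, or 5 and 1 over the list alone (median 0.27, camera adjusted p = 0.0112, adjusted p = 0.671 with an estimated correlation). Gclm and Gclc, which make glutathione, rose by 0.75 ± 0.16 and 0.73 ± 0.14. The cytosolic ribosomal list passed as higher with 2 up and 2 down of 85, the same over the list alone (median 0.19, camera adjusted p = 2.68e-07, adjusted p = 0.823 with an estimated correlation). Rpl34 rose by 1.13 ± 0.15. Rps2 fell (−1.11 ± 0.12) as its copy Rps2-ps13 rose, so Rps2 is uncertain. The EMT and matrix list passed as higher with 7 up and 4 down of 25, or 9 and 4 over the list alone, and its median of 0.21 and mean of −0.04 differ in sign (camera adjusted p = 0.0452, adjusted p = 0.719 with an estimated correlation). The protease gene Plau rose by 1.68 ± 0.20, and the mesenchymal genes Zeb1 and Vim fell (−2.27 ± 0.26 and −1.87 ± 0.20). Oxidative phosphorylation (2 up of 79, and 0 over the list alone, median 0.06), p53 and senescence (1 up of 21, 6 up and 1 down over the list alone, median 0.23) and mitochondrially encoded transcripts (median 0.18) passed as higher, each with camera adjusted p = 0.0258 and with adjusted p = 0.823, 0.671 and 0.823 with an estimated correlation. Their members Ndufa11 and Trp53inp1 rose by 0.62 ± 0.16 and 0.89 ± 0.16. Of the 14 mitochondrial transcripts 0 passed with limma or voom and 2 had an unadjusted p under 0.05, with mt-Rnr1 at 23285 ± 1660 against 16708 ± 3258. Without CD1 replicate 1 the camera adjusted p was 0.0833 for the pentose phosphate list, 0.133 for oxidative phosphorylation, 0.317 for p53 and senescence, 0.16 for EMT and matrix and 0.863 for mitochondrial transcripts, whose median became −0.07. Without mutant rapamycin replicate 2 it was 0.0778 for the pentose phosphate list, 0.0578 for p53 and senescence, 0.449 for EMT and matrix and 0.174 for mitochondrial transcripts, and without mutant rapamycin replicate 1 it was 0.354 for oxidative phosphorylation. The p53 median was 0.08 without CD1 replicate 1. Oxidative phosphorylation had medians of 0.01 and 0.16 without mutant rapamycin replicate 1 or 2, and 0.15 and 0.14 with the other scalings. The EMT median was 0.42, 0.37 and 0.07 without CD1 replicate 2 or mutant rapamycin replicate 1 or 2, and 0.47 with the stricter filter. The mitochondrial median was 0.39 without CD1 replicate 2 and 0.27 with median of ratios. The EMT list also did not pass with either other scaling or no filter, nor mitochondrial transcripts with either other scaling or the stricter filter. Calls of Anxa8, Gclc and Ndufa11 ended without CD1 replicate 2, those of Foxm1, Gclm, Ndufa11 and Trp53inp1 without CD1 replicate 1. Leaving out mutant rapamycin replicate 1 ended those of Anxa8, Mki67, Foxm1, Gclm, Gclc, Ndufa11 and Trp53inp1. Leaving out mutant rapamycin replicate 2 ended those of Anxa8, Gclm, Gclc and Trp53inp1. Other settings ended calls, with highest limma adjusted p = 0.167 for Anxa8 (voom).

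Among the lists that passed as lower, 6 of 25 cholesterol synthesis genes fell, and 8 over the list alone (median −0.66, camera adjusted p = 4.51e-06, adjusted p = 0.755 with an estimated correlation). Idi1 and Dhcr24 fell (−1.76 ± 0.40 and −1.40 ± 0.28). Of 38 interferon genes 3 fell, the same over the list alone (median −1.09, camera adjusted p = 0.00021, adjusted p = 0.823 with an estimated correlation). The CD1 libraries differed by 1.04 in this list, and its median was −0.55 without CD1 replicate 1 and −1.79 without replicate 2. Oasl2 fell from 633 ± 355 to 44.5 ± 0.7 and Xaf1 (−1.93 ± 0.31). Of 21 MHC class I genes 2 fell, the same over the list alone (median −0.37, camera adjusted p = 0.0258, adjusted p = 0.823 with an estimated correlation). B2m fell from 10943 ± 538 to 5159 ± 233. Immune cell markers had 3 of 21 genes down, the same over the list alone (median −0.6, camera adjusted p = 0.0674), with Laptm5 at 24.5 ± 7.8 against 64 ± 18.4. Of 24 luminal identity genes 7 fell and 3 rose, or 10 and 4 over the list alone (median −0.41, camera adjusted p = 0.0341, adjusted p = 0.671 with an estimated correlation). Agr2 and Prlr, the prolactin receptor gene, fell (−2.72 ± 0.26 and −2.33 ± 0.27). Of 18 secretory luminal markers 8 fell, and 13 over the list alone (median −2.44, camera adjusted p = 1.72e-10, adjusted p = 0.671 with an estimated correlation). Msmb fell from 5538 ± 1525 to 642 ± 24.7. Of 14 endothelial markers 10 fell, and 13 over the list alone (median −1.89, camera adjusted p = 2.09e-07, adjusted p = 0.671 with an estimated correlation). Kdr and Flt1 fell (−2.82 ± 0.44 and −2.48 ± 0.29). Of 20 stromal markers 9 fell and 1 rose, or 12 and 4 over the list alone (median −1.24, camera adjusted p = 0.00211, adjusted p = 0.671 with an estimated correlation). Col6a3 fell (−3.04 ± 0.47), and Thy1 rose by 2.37 ± 0.26. Without mutant rapamycin replicate 1 the luminal and MHC class I lists did not pass (camera adjusted p = 0.0646 and 0.153), nor the luminal list with no filter (camera adjusted p = 0.103). Without mutant rapamycin replicate 2 the luminal median was −0.63, and without CD1 replicate 1 the MHC class I median was −0.24. Calls that ended when 1 library was left out had limma adjusted p = 0.116 for Idi1, 0.076 for Dhcr24 and 0.226 for Laptm5 without CD1 replicate 2, 0.193 for Idi1, 0.0954 for Dhcr24, 0.0936 for Oasl2, 0.0803 for Laptm5 and 0.0988 for Col6a3 without mutant rapamycin replicate 1, 0.14 for Idi1, 0.129 for Dhcr24, 0.0891 for Oasl2, 0.205 for Laptm5 and 0.07 for Col6a3 without mutant rapamycin replicate 2, and 0.0664 for Laptm5 without CD1 replicate 1. Calls also ended, with highest limma adjusted p = 0.0877 for Idi1 (voom, block, both other scalings), 0.102 for Oasl2 (voom), and 0.0662 for Laptm5 (voom, only 4 libraries, block, both other scalings, not robust).

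NF-kB targets did not pass, with 0 up and 4 down of 31, or 1 and 5 over the list alone (median −0.26, camera adjusted p = 0.449). Nfkbiz and Birc3 fell (−0.80 ± 0.13 and −0.75 ± 0.13). The call of Nfkbiz ended without mutant rapamycin replicate 2. That of Birc3 ended without CD1 replicate 2 and also without mutant rapamycin replicate 1. Rising and falling genes of the other lists that did not pass numbered 4 and 4 of 17 for proximal luminal progenitors (4 and 6 over the list alone), 2 and 3 of 26 for innate immune genes (2 and 6), 2 and 1 of 30 for chemokines and cytokines (2 and 2), and 0 and 1 of 16 for IL-17 signalling (1 and 2). They numbered 0 and 3 of 23 for JAK-STAT3 signalling (0 and 3), 4 and 7 of 28 for FoxO targets (5 and 7), 2 and 1 of 22 for glycolysis (2 and 1), 0 and 3 of 21 for fatty acid synthesis (0 and 3), and 3 and 7 of 32 for ATF4 targets (3 and 11). They numbered 2 and 6 of 38 for lysosome and autophagy (3 and 8), 2 and 4 of 22 for hypoxia (4 and 5), 0 and 3 of 19 for EGFR genes (0 and 3), 3 and 0 of 31 for PI3K and mTOR components (4 and 1), 5 and 7 of 32 for Notch, Wnt and Hedgehog genes (8 and 9), and 0 and 4 of 28 for dissociation genes (0 and 4). Of 36 ribosome biogenesis and MYC target genes 0 passed with limma or voom, and 5 had an unadjusted p under 0.05. The camera adjusted p of these lists lay between 0.232 and 0.957, and the median or mean and the test differed in sign for proximal luminal progenitors, IL-17 signalling, glycolysis, ribosome biogenesis, PI3K and mTOR components, and Notch, Wnt and Hedgehog genes. Of the lists too small to test, 2 of 4 seminal vesicle and urethral genes fell, and the neuroendocrine and red blood cell lists had 0 called genes with limma or voom and 2 and 0 at an unadjusted p under 0.05, and over the list alone 1 neuroendocrine gene rose and 1 fell. Lists that passed with a library left out were immune cell markers as lower (medians −0.84, −0.65, −0.63 and −0.92) without CD1 replicate 2, mutant vehicle replicate 1, mutant vehicle replicate 2 or mutant rapamycin replicate 1, glycolysis (0.14) without CD1 replicate 2, chemokines (0.36) without mutant rapamycin replicate 1, and EGFR and dissociation genes as lower (−0.24 and −0.33) without mutant rapamycin replicate 2. Immune cell markers also passed as lower with either other scaling, only 4 libraries or the replicate block, and chemokines as higher (0.35) with the stricter filter.

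The counts were 244 up and 381 down without mutant rapamycin replicate 1, 388 and 414 without mutant rapamycin replicate 2, 390 and 395 without CD1 replicate 1, and 436 and 561 without CD1 replicate 2. Of 115 genes named by the rule and past the threshold, 71 lost the call when some library was left out, with the direction the same in each. Under alternatives that left out no library 27 lost it, 16 of them with voom.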

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

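Of the alternatives below, trimmed-mean scaling and the use of reads without rounding up were chosen after the data were seen, and the others before. The planned count-based fits were not run, because the values are not counts, and the alternatives that belong to them were carried over to limma where limma offers them.

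With median-of-ratios scaling 2944 genes rose and 2940 fell in mutant vehicle versus CD1, 1183 and 1165 in mutant rapamycin versus mutant vehicle, and 885 and 902 in mutant rapamycin versus CD1, against 2741 and 2894, 982 and 1505, and 693 and 1144 with the deposited scaling. Trimmed-mean scaling gave 2945 and 2947, 1168 and 1180, and 878 and 907. The median log2 fold change of all genes was −0.004, −0.077 and −0.081 with the deposited scaling and 0.002, −0.005 and −0.002 with trimmed means. limma voom on the same values gave 2692 and 2884, 836 and 1430, and 606 and 1159. With these alternatives, and with no filter, a filter of 5 CPM, only the 4 libraries compared, no robust estimation, a pseudocount of 0.1 and reads without rounding up, the counts of genes stayed within 1.5 times the reported ones. The filter of 5 CPM called 15, 16 and 16 lists and no filter 23, 17 and 14. The median response of genes that rose, against the held-out vehicle library, was −0.62 as a mean over both libraries and −0.82 without the filter, and the cause was not tested.

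Asking for at least a 2-fold change left 1302 genes up and 1802 down in mutant vehicle versus CD1, 440 and 814 in mutant rapamycin versus mutant vehicle, and 378 up in mutant rapamycin versus CD1, where 811 fell. The overlaps became 569 genes that rose and then fell and 361 that fell and then rose.

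With an estimated correlation 0 lists passed in any comparison, where camera at its preset correlation called 19, 17 and 16. With the estimate 2 lists in each had an unadjusted p under 0.05. The estimated form also takes its p from a t distribution with the 3 residual degrees of freedom, which the preset form does not. Higher correlations therefore do not account for all lost lists. Basal identity in mutant rapamycin versus CD1 had an estimated correlation of −0.009, below the preset, yet unadjusted camera p rose from 2.09e-07 to 0.0104.

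Leaving out each library in turn leaves a group with 1 library, which is then assumed to vary like the other groups. In mutant vehicle versus CD1 the genes that rose numbered between 1335 and 2742 and those that fell between 1500 and 2814, with the lowest counts without mutant vehicle replicate 1 and without CD1 replicate 1. In mutant rapamycin versus mutant vehicle the ranges were 241 to 1074 and 354 to 1484, lowest without mutant rapamycin replicate 2 in both. In mutant rapamycin versus CD1 they were 244 to 717 and 381 to 1337, lowest without mutant rapamycin replicate 1 in both. Genes that rose and then fell with rapamycin numbered 251 to 1098, lowest without mutant vehicle replicate 1, and genes that fell and then rose 204 to 899, lowest without mutant rapamycin replicate 2. Fewer libraries alone lower such counts and can end the calls of single genes. Lists past the threshold numbered 17 to 23, 17 to 20 and 11 to 18. The list of mitochondrially encoded transcripts in mutant rapamycin versus CD1 had medians between −0.07 and 0.39, and it reversed without CD1 replicate 1 (−0.07, adjusted p = 0.863 in camera of limma); the cause was not tested.

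Samples of the groups share replicate numbers but no label pairs them. The deviations of same-numbered samples from their group means correlated at −0.02, 0.12 and 0.17 across genes, so the numbers were not taken as pairs. With a replicate block 2999 genes rose and 3076 fell in mutant vehicle versus CD1, 1141 and 1872 in mutant rapamycin versus mutant vehicle, and 822 and 1306 in mutant rapamycin versus CD1. The block gave 19, 17 and 17 lists, and overlaps of 1380 and 912 genes.

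For single genes named by the rule, 6169 alternatives were computed: 5483 left direction and call as reported, 674 ended the call, 12 gave a call where there was none, and 0 reversed a direction. For lists the numbers were 1632, 1508, 87, 36 and 1. The depth, between 13761287 and 18279236 reads, sets the lowest values: 1 read is between 1.0941 and 1.4534 units, so genes near the filter of 20 units rest on few reads.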

Other observations

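Of the tests below, those of pseudogenes, of immune cells and of variation between libraries were chosen after the results were seen, and the gene families and single genes in the next paragraph were picked after the data were seen.

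Genes of the Hist symbols, most of them replication-dependent histones, moved together. Of 60 tested, 48 rose in mutant vehicle against CD1 and 1 fell (median log2 fold change 2.2), and 44 fell with rapamycin (median −1.3). Hist1h3c had 72.5 in CD1, 1198 in mutant vehicle and 310 in mutant rapamycin. The replication-dependent ones lack a poly(A) tail, so their level may depend on how the libraries were made. Cell cycle genes moved likewise (medians 2.36 and −1.52). Of 10 Psmb genes, which encode proteasome subunits, 9 rose in mutant vehicle (median 0.8) and 6 fell with rapamycin (median −0.66). Of 37 genes of the Col symbols, most of them collagens, 20 fell and 5 rose (median −1.3), while Col8a1 rose from 128.5 to 4136. Among those that fell were Col1a1, Col1a2, Col3a1 and Col6a3, which are also in the stromal marker list. The directions of these families were the same with both other scalings. In total 240 families were tested, so these are picked from many.

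Markers of endothelial, secretory luminal and stromal cells were lower in mutant vehicle than in CD1. If cells of another type were only rarer, their markers would fall by about the same amount, so the SD of the markers' log2 fold changes was set against their median SE. For 18 stromal markers the ratio was 3.89 (changes from −2.88 to 2.27). Risen markers raise it, so fewer stromal cells may still explain those that fell. For 13 endothelial markers it was 2.13 (changes from −3 to 0.37) and for 18 secretory markers 2.66 (changes from −4.7 to −0.8), between the bounds set for the test, so a larger share of these cells, or of their free RNA, in the CD1 libraries may account for the lower markers and cannot be told apart from lower expression in the basal cells. The most abundant markers were Tgm4 (54665.5 in CD1, 3405.5 in mutant vehicle), Dcn (47616 and 49861) and Ramp2 (753 and 971.5). Of these lists 2 secretory genes and 1 stromal gene are in other lists as well. The sort for basal cells was meant to remove such cells, yet Tgm4 lay above Krt5, Krt14 and Trp63 in the CD1 libraries. Strain and genotype remain open as well, both untested.

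Genes that differed from CD1 alike in both mutant groups and not between them numbered 885, of which 314 were higher and 571 lower. Within 10 Mb of Pten or Rosa26 lay 10 of them (1.13%, against 1.54% of the other tested genes). The odds ratio was 0.73 (95% interval 0.35 to 1.37, Fisher's exact test p = 0.398). With 267 tested genes there, this argues against flanking DNA as a main source. Annotated pseudogenes made up 30 of them (3.39%), against 24 (0.97%) of the genes that rapamycin changed, an odds ratio of 3.6 (2.02 to 6.47, Fisher's exact test p = 5.25e-06). Strain variants that move reads between genes and their copies may thus explain some of these genes, though pseudogenes are a small share of the 885. A lasting effect of the genotype that rapamycin leaves in place remains open and was not tested.

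The interferon list was lower with rapamycin than with vehicle. The 7 pan-haematopoietic genes fell by less: their median lay 1.74 above that of the interferon list, against an SD of 1.72 over the interferon genes. These genes had a median of 37.5 and at most 88 units in mutant vehicle, against 570 for the interferon list, so a loss of immune cells may still contribute. The condition that the genes lie above 100 units was added after the value of 1.74 was seen, and without it the test would have argued against immune cells. The median gap between libraries of 1 group reached 0.56 of the gap between the groups. With an estimated correlation, on 3 residual degrees of freedom, the camera p was 0.1796 before adjustment. Variation between samples could therefore not be told apart from an effect of rapamycin.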
